A study of Danio rerio with 2 samples.

How the data were processed

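Liver RNA of wild-type zebrafish was measured in 2 libraries, 1 from fish exposed to sodium arsenate and 1 from water controls, as the labels assign them. Libraries were built by a service company for the SOLiD system and 3' SAGE tags were sequenced, per the labels' protocols and design text. The authors deposited 1 table per library with a value headed TPM for each of 17991 transcripts. These values were read as RPM, with each tag a read, as deposited by the authors, because each is a whole multiple of 1 constant and each column sums to the same total, with no length scaling visible. The tag mapping tool, the reference release, any filter and any pooling of fish are not given in the sources used here, and neither is the genome build, so no coordinates are reported.

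Whole tags were recovered from the values: 100% of them were whole multiples of the value of 1 tag within 0.01 tags. The totals were 4420935 tags for arsenate and 2592679 for water, a 1.71-fold difference in depth. The files list 12397 transcripts with a tag in the arsenate library and 11844 in the water library, and 3909 transcripts are blank in both. A blank was taken as 0 tags, for which 3 tags, or 0.679 RPM for arsenate and 1.16 RPM for water, is the limit used.

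Transcripts carry a GI number and, for 10556, a RefSeq accession. Of those, 9463 matched a gene symbol in a RefSeq gene table of assembly GRCz12tu, used only for names, and 1093 did not, while 7435 rows have a GI number alone. Rows sharing a symbol (56) were summed, giving 17963 genes, 14068 with a tag and 7839 with at least 10 tags, of which 5886 have a symbol. Matched rows hold 73.2% of the arsenate tags and 81.3% of the water tags. Tags of paralogs and multigene families could have been split or shared in the authors' mapping, so ferritin, cytochrome P450, glutathione S-transferase, vitellogenin, trypsin and elastase genes are uncertain one by one.

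The design was written for counts, while the files hold RPM, so the fallback named in it became the main result: genes with at least 10 tags and a ratio of RPM + 1 of at least 2 or at most 0.5. This scale understates the change of low genes. The design's test for counts was an exact two-sided binomial test with Benjamini-Hochberg adjustment at 0.05 and a ratio of at least 2. Its use on the recovered tags, beside the fallback, was decided after the data were seen. With 1 library per group no replicate error can be estimated, and this test compares the libraries, not the conditions. Ratios without the added 1 are given with 95% intervals from the Clopper-Pearson interval of the arsenate share of a gene's tags. These treat each tag as an independent draw and cover counting error only. PCR copies are not independent molecules, so the intervals are too narrow where tags are such copies. Shares of tags have exact Clopper-Pearson intervals.

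Gene lists, the rule for named genes, the thresholds and most alternatives were chosen before the data were examined. There were 21 pathway lists and 15 lists of cell type markers. For each list with at least 3 measured members, the median log2 ratio (0.5 prior count) was placed among 10000 random lists of the same size matched in 20 bins of expression, and a list below percentile 2.5 or above 97.5 was said to stand apart. This percentile describes these libraries and is not a p-value. Random lists could include members of the list itself. Named genes were the 12 highest and 12 lowest by the interval bound nearer to 1, among genes past the exact test with a mean of at least 20 RPM, the 6 with the largest difference in each direction, the 2 list members with the most tags, and up to 2 pathway list members past the test with the bound farthest from 1. Genes known only by a clone-type name or identifier were counted but not named: 9 among the genes higher and 3 among those lower were passed over in the ranking, and 93 of 376 and 94 of 369 genes past the test at that level had no usable name. The result of 1 gene that this rule selects is not reported here. Ranked by the ratio of RPM + 1, 11 of the 12 genes higher and 12 of the 12 lower were the same.

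Alternatives were TMM scaling (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), totals without the 10 most abundant genes of each library, minimums of 1 and 50 tags, folds of 1.5 and 4, pseudocounts of 0.1 and 5, a prior count of 5, thinning of the deeper library, the transcript with most tags in place of the sum, unmatched random lists, and edgeR's exact test with an assumed coefficient of variation of 0.2 or 0.4. The edgeR and DESeq2 steps ran in R 4.3.3 on the recovered tags, and the rest in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

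The steps were tested on simulated libraries of the same depth, with 7839 genes tested and 200 changed. All simulated tags were recovered from such values. The ratio rule called 95 of 100 genes changed 4-fold, 40 of 98 changed 2-fold and 158 of 7641 unchanged genes, and the exact test 81, 21 and 2. Of 100 random lists of 30 unchanged genes, 3 stood apart, and a list raised 1.5-fold lay at percentile 100. Unchanged genes in the simulation differed by counting error only. The real log2 ratios spread more widely, from -0.65 at the 25th percentile to 0.75 at the 75th. The simulated rates of calls and the percentile of the raised list therefore do not carry over to the real libraries.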

Results

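Liver RNA from adult wild-type zebrafish was profiled by 3' SAGE, which counts a short sequence tag from the 3' end of each transcript. Fish aged 3 months were exposed to sodium arsenate for 96 h, with about 15 adults per 3 L tank, and sibling fish were kept in water. The design asks which genes and pathways differ in liver after arsenic exposure. It holds 1 arsenate library of 4420935 tags and 1 water library of 2592679 tags, so no difference below has a replicate check. Values are in RPM, tags scaled to a common library total, where 1 tag was worth 0.226 RPM in the arsenate library and 0.386 RPM in the water library. Intervals are 95% intervals of the ratio and cover only the counting error of independent tags.

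As lists, proteasome, glutathione and endoplasmic reticulum stress genes were higher in RPM in the arsenate library than in the water library. Amino acid metabolism, sterol synthesis and ribosome genes were lower in RPM. The calls for endoplasmic reticulum stress and ribosome genes were lost under some alternatives. In each of these lists except amino acid metabolism, most measured members were within 2-fold. For amino acid metabolism it was 18 of 38. The largest ratio of a named gene belonged to the ferritin heavy chain-like gene fthl28, at 2610 RPM in the arsenate library and 5.40 RPM in the water library. Digestive enzyme genes of the exocrine pancreas moved in the other direction as a set, with 22 of 23 measured markers at least 2-fold lower in the arsenate library. Of 7839 genes with at least 10 tags over both libraries, 1222 (15.6%) were at least 2-fold higher and 1125 (14.4%) at least 2-fold lower, by the ratio of RPM + 1. An exact binomial test on the recovered tags, which compares these libraries and not the conditions, gave 1084 genes higher and 1065 lower. The genes higher made up 52.1% of the calls by the ratio. That share was 63.3%, with 1680 genes higher and 975 lower, when the libraries were scaled without the 10 most abundant genes of each.

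**Figure D1:**
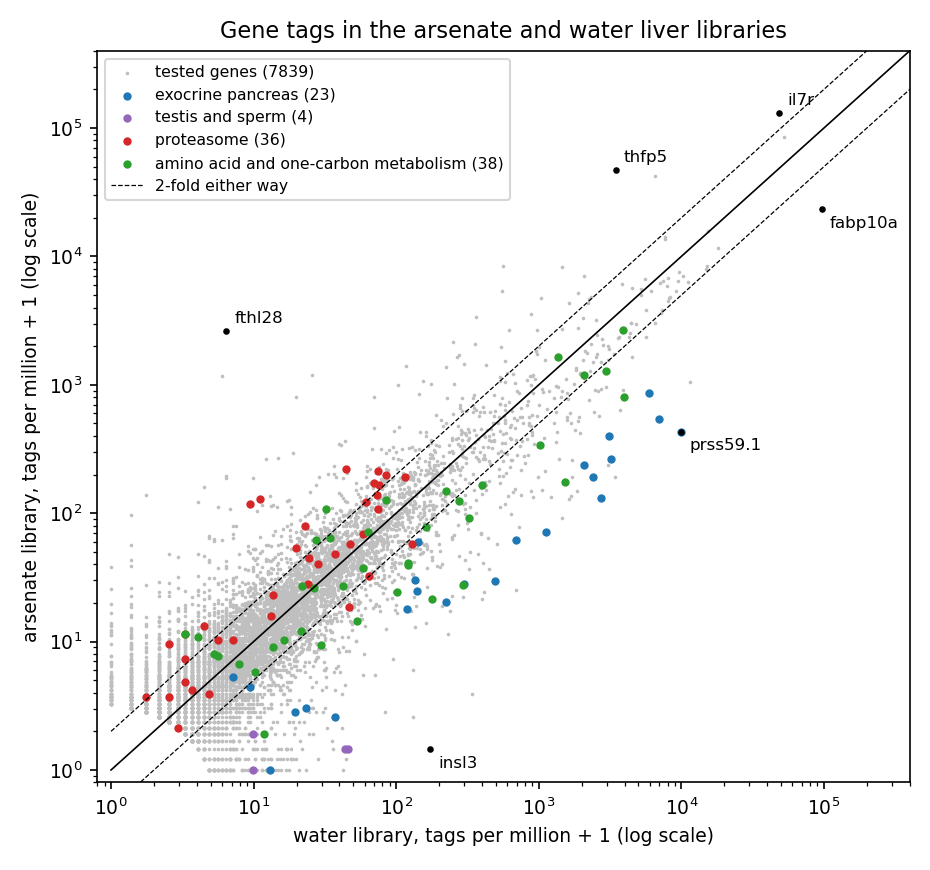
RPM + 1 of each tested gene in the water library (x axis, log scale) and the arsenate library (y axis, log scale). Each point is 1 gene, the solid line marks equal values and the dashed lines mark a 2-fold ratio, and 22 of the 23 exocrine pancreas markers lie beyond the lower dashed line.

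Among named genes ranked by the interval bound nearer to 1, fthl28 was 483-fold higher in the arsenate library (288 to 884), from 11538 tags against 14. The lect2.3 gene, of the family of leukocyte-derived chemotaxin 2, stood at 1186 RPM against 24.7 RPM, 48.1-fold higher (37.6 to 62.5). The monocarboxylate transporter family gene slc16a9a was 35.9-fold higher (21.3 to 65.9) and the cytochrome P450 gene cyp2aa7 34.6-fold higher, at 187 RPM against 5.40 RPM. The glutathione S-transferase gene gsta.2 had 185 tags against 1, a ratio of 108 (19.2 to 4308), and the muscle methyltransferase gene smyd1a 603 tags against 2, a ratio of 177 (48.7 to 1463). The other genes of this ranking were card9, an adaptor of innate immune signalling, pon1, a paraoxonase, rbm41, klf11b, acat2 and thfp5, with ratios from 13.6 (thfp5) to 23.8 (klf11b). By difference in level among named genes, the transcript listed as il7r was highest, at 130132 RPM against 48343 RPM, followed by thfp5 at 46938 RPM against 3454 RPM. The intelectin gene itln3 reached 8334 RPM against 1458 RPM, the fibrinogen gene fgg 13615 RPM against 7653 RPM (1.78-fold), the keratin gene krt18a.1 4765 RPM against 1043 RPM, and the antiplasmin gene serpinf2b 3352 RPM against 360 RPM. Tags of fthl28, lect2.3, cyp2aa7 and gsta.2 may be shared with close copies of these genes, which leaves their individual values uncertain. Skeletal muscle markers did not move with smyd1a as a set. Of 3 measured, acta1a was at least 2-fold higher, actc1b at least 2-fold lower and ckmb neither. The tag sequences behind smyd1a were not examined here, so its value is uncertain too.

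The lowest ratios included genes of testis. The hormone gene insl3 of Leydig cells had 2 tags in the arsenate library and 444 in the water library, a 379-fold difference (104 to 3135). The meiotic chromosome genes hormad1 and sycp1 and the cilium and flagellum gene tekt1 were at 43.2, 44.7 and 42.4 RPM in the water library and at 1 or 2 tags in the arsenate library. The cerebellin family gene cbln9 was 116-fold lower (67.5 to 219) and the epidermal keratin gene krt5 28.4-fold lower (23.3 to 34.8). Digestive proteases were next, with the trypsin family gene prss59.1 at 430 RPM against 10000.5 RPM, 23.2-fold lower (22.2 to 24.4), and the elastase ela2l 21.02-fold lower (19.3 to 22.9). The gluconeogenesis gene fbp1b was 19.4-fold lower (15.7 to 24.4), dio2, which activates thyroid hormone, 17.96-fold lower (16.7 to 19.3), and the carboxylate transporter gene slc13a2 26.0-fold lower (16.9 to 42.1). The translation-linked kinase gene mknk2a was 22.1-fold lower (16.4 to 30.6). In absolute level the liver fatty acid binding protein gene fabp10a was the furthest below its water value, at 23450 RPM against 96575 RPM, 4.12-fold lower (4.09 to 4.15). After fabp10a and prss59.1, the plasma protein genes ahsg1 and apobb.1, the elastase cela1.6 and the ribosomal gene rplp0 followed by difference, at 1.86, 1.81, 12.9 and 1.55-fold lower.

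**Figure D2:**
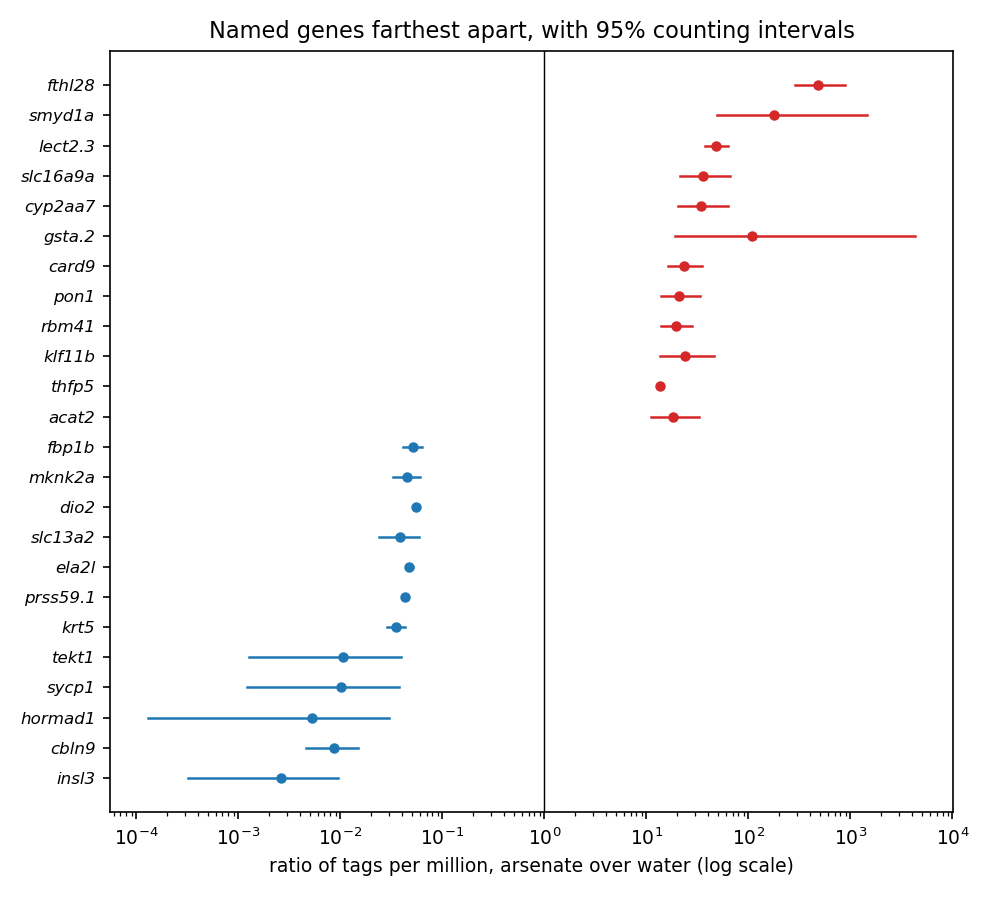
Ratio of RPM, arsenate over water (x axis, log scale), for the 12 named genes ranked highest (red) and the 12 ranked lowest (blue), with 95% counting intervals as lines. Ratios run from 483 for fthl28 down to 12 genes below 1, and the intervals are widest for genes with 1 or 2 tags in 1 library, such as gsta.2 and hormad1.

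Proteasome genes, which encode the protease that degrades ubiquitin-tagged proteins, were higher in the arsenate library. Of 36 measured members, 14 were at least 2-fold higher, 2 at least 2-fold lower and 20 neither, and 31 had a ratio above 1. Their median ratio was 1.79, or 0.84 on the log2 scale, at percentile 99.98 among 10000 random lists matched on expression. The core subunit gene psmb4 stood at 117 RPM against 8.49 RPM and the ubiquitin receptor gene psmd4a at 128 RPM against 10.03 RPM, while psmc1b was 2.86-fold higher (2.44 to 3.35) and psmd14 1.68-fold higher (1.47 to 1.92). The 2 members at least 2-fold lower were pomp and psmb2, named after their values were seen. Exocrine pancreas markers moved the opposite way in the same comparison, at 0.341% of tags in the arsenate library and 3.98% in the water library.

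Genes of the NRF2 and glutathione response, which detoxify electrophiles and oxidants, had a median log2 ratio of 0.59 at percentile 98.0. Of 23 measured, 8 were at least 2-fold higher, 2 lower and 13 neither. The glutathione reductase gene gsr had 18.8 RPM against 0.386 RPM, the ferritin gene fth1a was 5.84-fold higher (5.46 to 6.26), and gstp1.2 was at 1822 RPM against 951 RPM. The members lower were gstr and the heme oxygenase gene hmox1a, at 46.4 RPM against 110 RPM, both named after their values were seen. Endoplasmic reticulum stress genes had a median of 0.40 at percentile 98.4, with 7 of 36 higher, 3 lower and 26 neither. The chaperone cofactor gene sdf2l1 was 6.74-fold higher (4.16 to 11.6) and the calreticulin gene calr3b 4.23-fold higher (3.24 to 5.61), while ssr2 and p4hb differed by less than 1.5-fold. The percentile of this list was 95.5 against random lists not matched on expression. Pancreas markers were lower beside both of these lists, at a median log2 ratio of -3.46.

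Iron handling and heme synthesis genes lay within the range of random lists, with a median of 0.37 at percentile 93.5 and 6 of 23 higher, 3 lower and 14 neither. The iron exporter gene slc40a1 was 10.7-fold higher (7.17 to 16.7), next to fthl28 and fth1a. Antioxidant enzymes and metallothionein also lay within, with a median of 0.30. The metallothionein gene mt2, which binds heavy metals, stood at 2688 RPM against 620 RPM, 4.34-fold higher (4.12 to 4.57), and selenop, the selenium transport protein gene, was 6.95-fold lower. The abundant glutathione peroxidase gene gpx4a had 15730 RPM against 15428 RPM, a ratio of 1.02 that turned to 0.983 with TMM scaling.

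Amino acid and one-carbon metabolism, a main task of hepatocytes, was lower in the arsenate library. Of 38 measured genes, 16 were at least 2-fold lower, 4 higher and 18 neither, and the median was 1.69-fold lower (-0.75 on the log2 scale), lower than in all 10000 matched random lists. The tryptophan oxidation gene tdo2b was 10.95-fold lower, the phenylalanine hydroxylase gene pah 8.75-fold lower at 173 RPM against 1516 RPM, and ahcy, which clears S-adenosylhomocysteine, 4.94-fold lower at 806 RPM against 3986 RPM. The betaine methyltransferase gene bhmt was at 2663 RPM against 3888 RPM. Cytochrome P450 and conjugation genes had a median of -0.54 at percentile 0.19, with 9 of 37 lower, 5 higher and 23 neither. The bile acid synthesis gene cyp7a1 had 2 tags in the arsenate library and 38 in the water library, while cyp2aa7 in the same list was among the genes highest in the arsenate library. Fatty acid and sterol synthesis had a median of -0.48 at percentile 1.25, with 5 of 24 lower, 2 higher and 17 neither, among them the desaturase gene fads2, 3.12-fold lower (2.63 to 3.72), and cyp51, 3.80-fold lower (2.92 to 4.99). Exocrine pancreas markers were lower beside these lists too, by 11.7-fold in their summed RPM.

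Cytosolic ribosomal protein genes took 13.4% of tags in the arsenate library and 18.8% in the water library. Their median log2 ratio was -0.55 at percentile 2.13, and 56 of 71 had a ratio below 1, although 57 were within 2-fold, 9 were lower beyond it and 5 were higher. The genes rpl26 and rpl18 were 12.8-fold and 12.6-fold lower. Ribosome biogenesis genes had a median of -0.48 at percentile 0.66, with 5 of 29 lower, 1 higher and 23 neither, including the helicase gene ddx21, 3.82-fold lower (3.32 to 4.41), and nop10, 3.90-fold lower (2.98 to 5.14). Cell cycle and DNA replication genes had a median of -0.73 at percentile 1.38, but 13 of 17 were within 2-fold. The spindle checkpoint gene mad2l1 had 2 tags against 29 and the mitotic kinase gene aurka 2 against 12. Exocrine pancreas and testis markers were lower beside these lists, at medians of -3.46 and -6.07. These calls did not hold under every alternative: the ribosomal protein list lay at percentile 7.63 with at least 50 tags per gene, and ribosome biogenesis at 2.62 with a prior count of 5. With at least 50 tags the ribosomal protein median was still -0.55, and the random lists it was compared with could hold its own members. The cell cycle list lay at percentile 37.0 with the 6 members that had at least 50 tags, and at 3.035 without the genes of the pancreas, islet, intestine, ovary and testis lists.

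Other pathway lists lay within the range of random lists. Vitellogenins and estrogen targets, the egg yolk precursor genes made in female liver, had a median of -1.20 at percentile 3.40, with 4 of 7 lower, among them vtg4, 2.71-fold lower, and vtg5, 2.77-fold lower. Tags of near-identical vitellogenin copies may be shared. Translation factors had a median of -0.40, with eef1a1l1 at 5381 RPM against 9119 RPM and eef1a1l2 at 3564 RPM against 877 RPM. Plasma proteins and coagulation had a median of -0.37, with 5 of 36 higher, such as serpinf2b, and 8 lower, such as apoa1a, 5.83-fold. Genes of p53 targets and apoptosis had a median of 0.41, with 6 of 19 higher, such as mdm2 and gadd45ga, and 2 lower. Cytosolic and mitochondrial chaperones had a median of 0.08, with 2 of 30 higher and 5 lower, among them hspa9 and fkbp5. Oxidative phosphorylation had a median of 0.06, with 5 of 61 genes higher and 5 lower. The remaining medians were -0.13 for fatty acid oxidation and PPAR targets, -0.07 for complement and acute phase, -0.05 for mRNA splicing and -0.04 for glycolysis and gluconeogenesis, all close enough to 0 for their sign to depend on the scaling. The last list includes fbp1b.

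**Figure D3:**
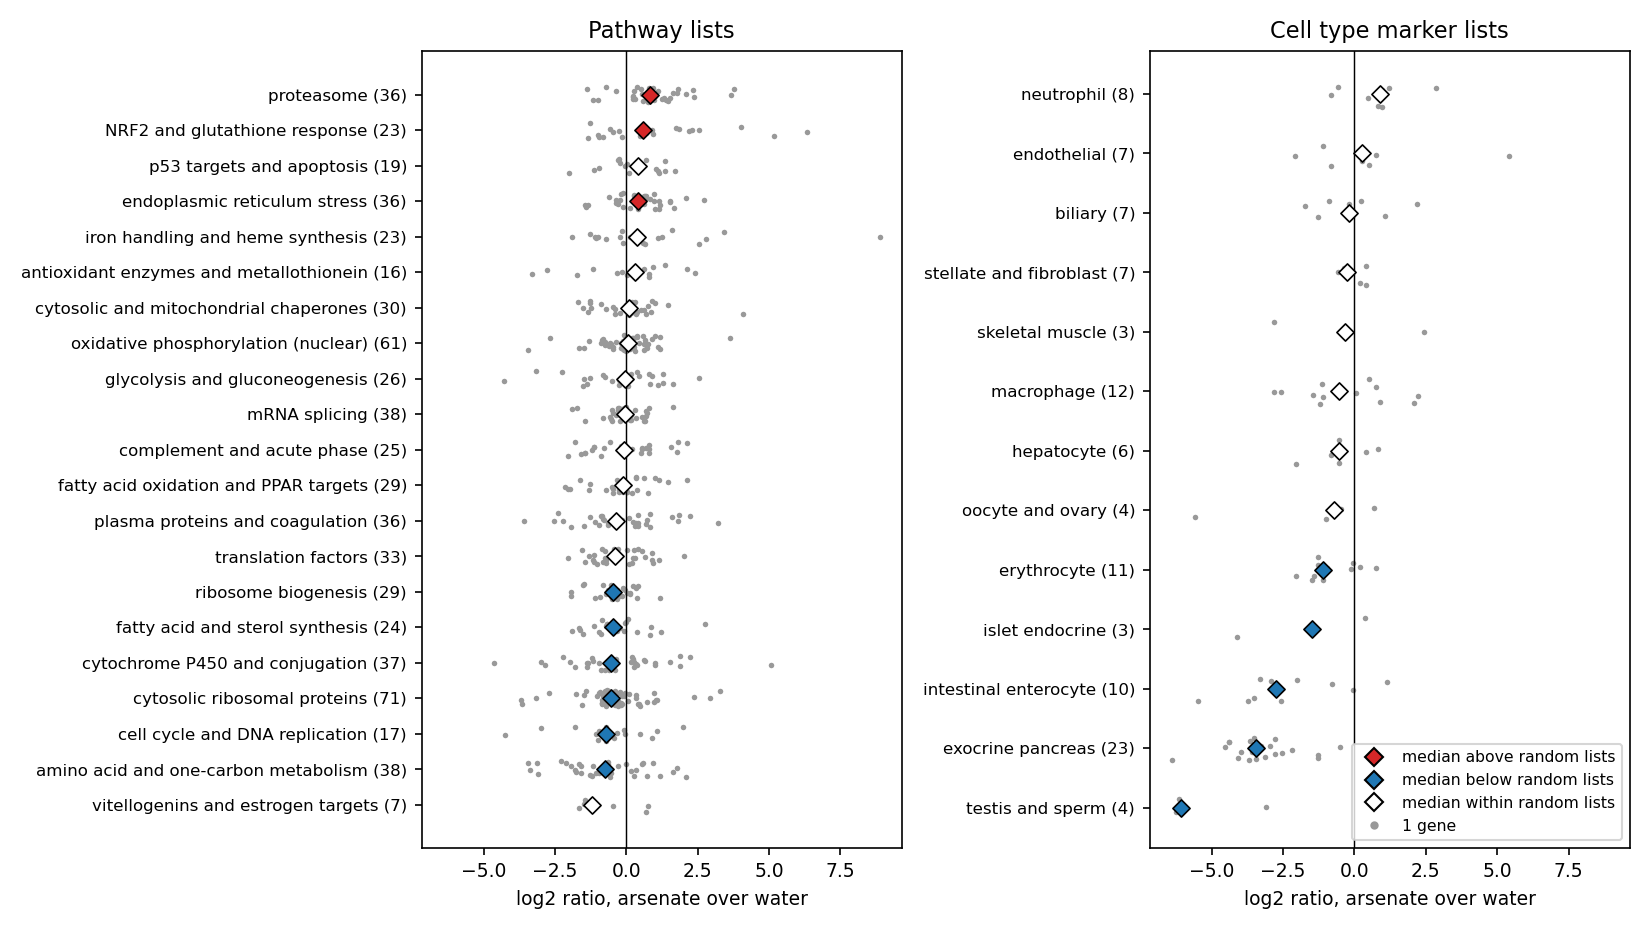
Log2 ratio of arsenate over water (x axis) for the members of each pathway list (left) and cell type marker list (right) with at least 3 measured members. Grey points are genes, diamonds are medians, and red and blue diamonds mark medians in the top or bottom 2.5% of matched random lists, with 3 lists above and 6 below on the left and 5 below on the right.

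Markers of neighbouring tissues differed between the libraries. All 23 measured exocrine pancreas markers had a ratio below 1, with a median log2 ratio of -3.46, below all of the random lists, and those with the most tags were prss59.1 and cela1.6. The testis and sperm list had a median of -6.07 over 4 genes, or -4.93 with the gene lacking tags in the arsenate library set at 3 counts. The intestinal enterocyte list had a median of -2.74, with 7 of 10 lower and 1 higher. Its 2 markers with the most tags, apoa4b.2 and tm4sf4, were within 2-fold, at ratios of 0.58 and 0.96. Islet markers had a median of -1.50 over 3 genes, with the glucagon gene gcga 2.84-fold lower, and lay at percentile 2.79 against unmatched lists. The islet marker ghrl had a ratio of 1.29 (0.745 to 2.31). Erythrocyte markers had a median of -1.11, with 6 of 11 lower, although the abundant globin genes hbba1 and ba1l were at 195 RPM against 201 RPM and 108 RPM against 117 RPM.

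The other marker lists lay within the range of random lists. Hepatocyte markers had a median of -0.55 over 6 genes, of which fabp10a alone was beyond 2-fold. The medians were -0.52 for macrophage, with the antigen presentation gene cd74b 6.04-fold lower and lgmn at 310 RPM against 184 RPM, and 0.90 for neutrophil, at percentile 97.3. Of 8 neutrophil markers, 6 had a ratio above 1 and 2 were at least 2-fold higher (lyz, 29 tags against 2, and mmp9, 44 against 11, named after their values were seen), while mpx, with the most tags, was at 29.2 RPM against 51.3 RPM. The medians were -0.20 for biliary (0.01 when scaled without the 10 most abundant genes), 0.28 for endothelial (-0.29 with the deeper library thinned), -0.28 for stellate and fibroblast (0.023 with thinning), -0.73 for oocyte and ovary and -0.35 for skeletal muscle cells. The lymphocyte list and the list of adipocyte and spleen or kidney neighbours had 2 measured members each and were not scored.

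A few genes held much of each library. The 10 most abundant took 39.1% of tags (39.1 to 39.2) in the arsenate library and 29.4% (29.3 to 29.4) in the water library, and 6 genes were among the 10 in both. The transcript listed as il7r alone took 13.01% and 4.83%, and fabp10a 2.35% and 9.66%. A transcript with no gene name took 8.51% and 5.26%. The gene names were matched from accession numbers, and the tag sequences behind il7r were not examined here, so its level should be read as that of the transcript as listed.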

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

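The use of the exact test on recovered tags and the removal of markers were decided after the data were seen, and the other alternatives before. Without replicates, none of them addresses variation between fish. Counts of genes higher and lower stayed within 1.5 times of 1222 and 1125 in 18 of 30 comparisons, including every scaling, and moved with the strictness of the rule: 713 and 565 with at least 50 tags per gene, 2176 and 1913 at 1.5-fold, 303 and 351 at 4-fold, 580 and 610 with a pseudocount of 5, 647 and 695 with an assumed coefficient of variation of 0.2, and 102 and 186 with 0.4. Without the pancreas, islet, intestine, ovary and testis markers they were 1163 and 1147. That removal took out the listed markers alone and left 7795 genes tested. Other transcripts of those tissues stayed in, so it could not show how much carried-over tissue matters. Scaling without the 10 most abundant genes raised the median log2 ratio of all genes by 0.22; the other scalings moved it by under 0.1. None of the 14 lists that stood apart changed sign, and 9 stood apart under all alternatives run on them, among them proteasome, NRF2, amino acid metabolism and exocrine pancreas. The ribosomal protein list lost its call with median-of-ratios factors (-0.59), at least 50 tags (-0.55) and thinning (-0.53), cell cycle at 50 tags (-0.069), without the markers (-0.63) and with a prior of 5 (-0.48), ribosome biogenesis with a prior of 5 (-0.32), and endoplasmic reticulum stress (0.40) and islet (-1.50) against unmatched lists. Lists that came to stand apart were vitellogenins without abundant genes in the scaling (-0.99), without markers (-1.38), with a prior of 5 (-1.20) and unmatched (-1.20), neutrophil without abundant genes (1.11), macrophage at 1 tag (-1.05) and at 50 (-0.52), skeletal muscle at 1 tag (-1.89), and translation factors (-0.40) and plasma proteins (-0.37) unmatched. The cause of these changes was not tested. At 50 tags the ribosomal protein list lost its call with 70 of its 71 members still measured and its median still at -0.55. The random lists were drawn from fewer genes there, its own members included. Without vitellogenins the 10 most abundant genes took 39.2% of arsenate and 29.5% of water tags. With TMM scaling 109 of 124 named ratios stayed within their intervals, 14 moved beyond them, and that of gpx4a turned from 1.02 to 0.983. Depth limits genes at 10 tags to large ratios, and a difference under a limit of 3 tags was not detectable.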

Other observations

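The tests in this part were chosen after the results were seen, except the spread of the pancreas markers and the removal of outlying proteasome genes. The gene families in this paragraph and the next were picked after their values were seen, so they are described and not tested. Of 14 measured vacuolar proton pump (atp6v) genes, which acidify lysosomes, 12 had a ratio above 1, with a median log2 ratio of 0.74, but 1 was at least 2-fold higher and 13 were neither higher nor lower by that much. Of 18 selenoprotein genes, 6 were at least 2-fold higher, 1 (selenop) lower and 11 neither, and 6 had a ratio below 1, with a median of 0.71, including txnrd3, 3.33-fold higher, and selenot2 at 242 RPM against 79.8 RPM.

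Of 10 measured clock genes, 5 were at least 2-fold lower and 1 higher in the arsenate library, with a median of -1.01. The period gene per1b was at 17.4 RPM against 59.0 RPM and the repressor gene nr1d1 2.62-fold lower, while nfil3, whose rhythm runs opposite to some of these genes, was at 9.50 RPM against 1.93 RPM. The time of day of sampling is not given in the labels. Of 8 keratin genes, krt18a.1 was 4.57-fold higher, 3 (krt8, krt92 and krt94) were within 2-fold, and 4 were lower: krt4 3.37-fold, while krt5, krt91 and krt97 were at 24.2, 11.99 and 12.9 RPM against 687, 135 and 161 RPM. The androgen synthesis gene hsd17b3, picked for its low ratio, was at 35.5 RPM against 446 RPM.

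Exocrine pancreas markers were lower in the arsenate library by a median log2 ratio of -3.46. Genes of carried-over tissue were predicted to share nearly 1 ratio. The interquartile range of the markers was 1.05, against a median of 1.37 for matched random lists, at percentile 16.01. This neither reaches the limit of 2.5 set for tissue carried over nor exceeds the 50 set against it. Single genes scatter within families in these libraries, and a response common to the markers could share a ratio as well. The range therefore could not separate these explanations. Carried-over tissue and a response to arsenate cannot be told apart with 1 library per group. Lower testis and intestinal genes in the same library may come from different dissection, and the testis genes also from a different sex ratio. The labels give neither. The vitellogenin genes vtg4 and vtg5, made in female liver, were 2.71-fold and 2.77-fold lower there too. A larger share of females in the arsenate sample would instead make them higher. Their tags may be shared between copies, and they do not settle the sex ratio.

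Single ribosomal protein genes lay far from the median of their family, with 7 of 71 more than 4-fold away, 3 of them above it (rpl23a, rps2 and rps26) and 4 below (rpl26, rpl18, rpl22l1 and rps21). Counting error would leave about 5% of the 95% intervals without the family median, but 62 of 71 left it out (87.3%), so counting error alone does not account for the spread. At these tag numbers the intervals are narrow, and the result says nothing about which other source is at work. The gene rpl23a, for example, had 4421 tags against 264, and rpl26 1051 against 7884. A sequence variant at the tag, tags shared with copies and a response of these genes to arsenate stay open, because tag sequences were not analysed here and there is 1 library per group.

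Proteasome genes were higher in the arsenate library by a median log2 ratio of 0.84. Their median lay above that of all tested genes by 0.788 at its lowest over the filters run, a difference that no scaling can make or remove because it moves all genes alike. Without the 5 members more than 4-fold apart, the other 31 had a median of 0.75 at percentile 99.9, so these 5 alone did not make the shift. A median hardly moves when 5 of 36 members are removed and 31 of the 36 have a ratio above 1. The removal therefore could not count against single-gene artefacts among the members. Dilution of hepatocyte transcripts by other tissue in the water library would raise hepatocyte lists as well, and the higher of the medians of plasma proteins and amino acid metabolism was -0.37, but members of both lists go both ways, so dilution is left open. A response of proteasome genes to arsenate is a candidate explanation that remains untested without replicates.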
